A study of Mus musculus with 12 samples.

How the data were processed

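RNA from the soleus of 12 mice in 4 groups of 3 was made into libraries with the KAPA stranded mRNA kit, per the labels' protocols. The labels name separate animals, and no batch, date or pairing. All animal numbers of the chow groups lie below those of the high-fat groups, with both genotypes in each range. Diet and the order of animal numbers therefore cannot be told apart. Per the submitters' processing notes, Bowtie2 2.1.0, RSEM 1.2.15 and edgeR (version not given in the sources used here) were used with the mm10 or GRCm38 build. The notes do not state the role or order of these tools, and which step made the p-values is not given in the sources used here. RSEM assigns reads shared between transcripts by expectation, so genes with near-identical copies are reported as uncertain.

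The 4 tables of the authors' comparisons hold, per the file headers, a total per gene, a p-value, a step-up adjusted p-value, a signed fold change and a log2 fold change. The totals are deposited as a signal, and their values show that the authors summed reads divided by library size factors over the 12 libraries, since the lowest totals take 12 values, each that of 1 read in 1 library. The p-value columns are those the authors deposited, and the adjusted values were recomputed from them by the Benjamini-Hochberg procedure with a largest difference of 3.7e-15. The log2 columns the authors deposited equal the log2 of the signed fold columns within 1.1e-14. Adjusted p-values were blank in the authors' deposited table for 14458 genes of G4 against G2, with totals up to 159.76, and for 11245 of G4 against G3, with totals up to 34.4, and these were kept as blank. The deposited table for G2 against G1 lists 15652 of 28997 genes, all with a log2 of 0 or below.

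Because the tables hold no values per library, the planned quasi-likelihood test of edgeR could not be run, and the authors' deposited p-values were used as theirs, which is the course fixed before the data were examined for that case. Standard errors were derived from each log2 and its p-value under a normal distribution, and are called implied standard errors. Positive values for G2 against G1 were rebuilt as G3 against G1 plus G4 against G3 minus G4 against G2, with the variance from the other 3 comparisons, and this was checked on the 7792 listed genes with a total of at least 100, where the log2 differed by at most 1.0e-14 and the log10 p by at most 2.8e-06. Over all listed genes 77.4% agreed within 0.01, so genes with a lower total were left out of rebuilt results, except Nox1. The total of Nox1 was 25.2, so its rebuilt value is uncertain. The smallest rebuilt p was 1.38e-04 and the smallest adjusted p 1.0. The interaction and averaged effects were rebuilt in the same way and adjusted over 15494 genes. The total of at least 100, a mean of 8.33 reads per library, was chosen after the data were seen. Rebuilding and the interaction were tested on simulated data with 100 of 15494 genes changed per fold size. At a fold of 2 the interaction recovered 54 and G4 against G2 recovered 65, at a fold of 4 they recovered 92 and 95, with 9 and 10 false calls. Size factors came from genes with 1 read, and the reads of Nox1 are the whole-number solution of its total, which recovered 10 of 10 simulated vectors. Genes that passed an adjusted p of 0.05 are called.

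Gene symbols were matched to GENCODE M21 on GRCm38, where 28063 of 28997 matched 1 gene and 15178 of the 15494 with a total of at least 100 (98.0%), and coordinates are 1-based. Lists fixed before the data were examined (38 with at least 5 members measured, among them fatty acid oxidation, PPAR targets, lipogenesis, glycolysis, slow and fast fibre, complexes of the respiratory chain, interferon response, ribosome and markers of adipocytes, macrophages, endothelial and erythroid cells) were tested with the camera test of limma 3.58.1 on z values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment per comparison. It recovered 5 of 5 shifted lists among 38 on simulated data and called 0 others. The simulated z values were independent between genes, so false calls from members that vary together were not tested. Counts adjusted over the list alone use only the p-values of the list's members. A median was set beside 10000 random lists, in which each member was replaced by a gene drawn within 100 ranks on either side of it by total. Trends of z on GC content, log transcript length and log total were removed with natural splines of 4 degrees of freedom each, which took 12.7% of the variance in G4 against G3, 10.0% in the interaction, 5.42% in G4 against G2, 3.32% in G3 against G1 and 1.69% in G2 against G1. Correlations between comparisons were set beside 100 simulated draws of unchanged groups with the implied errors, drawn independently for each gene.

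Named genes followed a rule fixed before the data were examined. It takes Nox1 and Cdh5, the 12 largest rises and 12 largest falls with an adjusted p under 0.05 and a mean of at least 5 CPM, without predicted genes and pseudogenes, or the 5 smallest p-values as not past the threshold where fewer than 5 pass, and up to 4 members of each list. The mean was taken over all libraries and not in the higher group, and the overlap of library values could not be examined. Alternatives were another threshold, a minimum fold of 1.5, other filters, p-values rescaled by the robust spread of z, trend removal, other preset correlations and ranks. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.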

Results

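The transcriptome of the soleus, a mouse hind limb muscle rich in slow oxidative fibres, was measured by stranded mRNA sequencing in 12 mice. The labels describe 4 groups of 3 mice each, which carried a Cdh5-driven Cre with or without a conditional Nox1 knockout and were fed chow or a high-fat diet for 8 weeks. Cdh5 is expressed in endothelial cells, and NOX1 is an NADPH oxidase that makes superoxide. Per the series title, the question was how endothelial NOX1 relates to obesity and to muscle mitochondria. The authors deposited 4 tables of their own comparisons between groups coded G1 to G4, for G2 against G1, G3 against G1, G4 against G2 and G4 against G3. No label ties a code to a genotype or a diet, and the order of groups in the design text and the order of the samples would give G2 and G3 opposite meanings. The groups are therefore named by code only, and no change below is assigned to the diet or to the knockout. Each table gave a value per gene and none per library, so mean and SD per group could not be computed. Totals summed over the 12 libraries came to 298863066 normalised reads over all genes, a mean of 24905255 per library. Library size factors recovered from genes seen as 1 read ran from 0.931 to 1.06 in G1, 0.986 to 1.25 in G2, 0.797 to 1.16 in G3 and 0.787 to 0.938 in G4. The median standard error implied by the deposited values was 0.176 to 0.178 on the log2 scale among the 15494 genes with a total of at least 100.

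Nox1 (chromosome X, 134086421 to 134221956, GRCm38) was close to undetected, with 26 reads over the 12 libraries. Its reads summed to 6 in G1, 10 in G2, 5 in G3 and 5 in G4. In the authors' deposited tables its log2 fold change was -0.23 for G3 against G1, -0.71 for G4 against G2 and 0.15 for G4 against G3, and the rebuilt value for G2 against G1 was 0.64 with a standard error of 1.22. A loss of Nox1 from endothelial cells was not detectable in whole muscle at this depth, and the gene could not check the labels. Cdh5 (chromosome 8, 104101625 to 104144511), at a mean of 173 CPM, had log2 fold changes of -0.09, 0.11, 0.23 and 0.04 in the authors' deposited tables for G2 against G1, G3 against G1, G4 against G2 and G4 against G3, with an implied standard error of 0.14, and none passed the test. The NOX family list fell in G2 against G1, with a median log2 of -0.19 and positive values in 2 of 8 members (set test adjusted p = 0.0165, and adjusted p = 0.302 with an assumed correlation of 0.2), while no single member was called, also adjusted over the list alone. Its members Rac2 and Ncf1, which phagocytes express, had log2 values of -0.78 and -0.64, and its member Nox4 had -0.42, in the authors' deposited table. Macrophage markers fell in the same comparison with a median of -0.34 and 0 of 14 positive (adjusted p = 1.04e-04, and adjusted p = 0.0942 with an assumed correlation of 0.2).

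Genes of fatty acid oxidation, which break down fatty acids in mitochondria and peroxisomes, were higher in G3 than in G1. All 21 measured members had positive values with a median log2 of 0.35, and 16 were called over all genes and 20 adjusted over the list alone. Decr1 (2,4-dienoyl-CoA reductase, chromosome 4, 15917240 to 15945507) rose by 0.67 with an implied standard error of 0.06 and an adjusted p of 1.26e-26 in the authors' deposited table. Ech1 rose by 0.71, Hadhb by 0.48 and Hadh by 0.39 in the authors' deposited table, although reads of Hadhb may be split with its near-identical copy Hadhb-ps, which rose by 0.50. Among targets of the lipid sensor PPAR, 3 of 16 were called, and 5 adjusted over the list alone. These were the acyl-CoA thioesterases Acot1 (chromosome 12, 84009490 to 84018371) and Acot2, which rose by 1.24 and 0.80, and the fatty acid binding protein Fabp3 with 0.59, which shares reads with Fabp3-ps1 at 0.58, all in the authors' deposited table. In the lipogenesis list 2 of 16 were called and 5 adjusted over the list alone, namely the transcription factor Srebf1 with a log2 of 1.01 and the desaturase Scd2 with 0.72 in the authors' deposited table. Set tests called fatty acid oxidation (adjusted p = 2.66e-84), PPAR targets (1.65e-10) and lipogenesis (2.31e-08) as higher.

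Genes of glucose use and fast fibres were lower in G3 than in G1. In the list of glycolysis and glycogen 1 of 20 had a positive value, the median log2 was -0.28, and 1 member was called, the lactate dehydrogenase subunit Ldhb with -0.21 in the authors' deposited table, against 9 adjusted over the list alone. The fast fibre list had a median log2 of -0.38 with no member called over all genes and 6 adjusted over the list alone, with Myl1 at -0.40 and Casq1 at -0.31 in the authors' deposited table. All 18 interferon response genes had positive values with a median of 0.56 and none was called, also adjusted over the list alone. The set test adjusted p was 7.64e-15 for glycolysis, 1.84e-11 for fast fibre and 9.46e-09 for interferon response. The 13 mitochondrially encoded genes had a median log2 of 0.14 (adjusted p = 4.36e-05, and adjusted p = 0.0563 with an assumed correlation of 0.2), whereas nuclear genes of respiratory complexes II to V had a median of -0.04 (adjusted p = 8.44e-04, and adjusted p = 0.551 with an assumed correlation of 0.2). Adipocyte markers had a median of -0.17 and an adjusted p of 0.149.

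In all, 61 genes passed an adjusted p of 0.05 in the authors' deposited table for G3 against G1, of which 49 rose and 12 fell. The other rises among the 12 largest under the naming rule were Chrna2, a nicotinic acetylcholine receptor subunit (1.26), the cholesterol exporter Abca1 (1.2), Rab15 (0.86), the lipid droplet protein Cidea (0.83), Reep6 (0.80) and Impa2 (0.70) in the authors' deposited table. Under the same rule the falls were led by the cytochrome P450 Cyp2e1 with -2.35 and an implied standard error of 0.55, followed by the potassium channel Kcnc4 (-1.23), Dupd1 (-0.72), pyruvate carboxylase Pcx (-0.51), the ketone body enzyme Oxct1 (-0.44), Rragd (-0.35) and Tuba4a (-0.34) in the authors' deposited table. With a fold change of at least 1.5 also required, 25 of the 61 genes were counted. Library values were not in the tables, so no mouse could be left out.

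PPAR targets and fatty acid oxidation genes were also higher in G4 than in G2. All 16 PPAR targets had positive values, the median log2 was 0.77, and 12 were called both over all genes and adjusted over the list alone (set test adjusted p = 1.06e-34). Angptl4 (chromosome 17, 33773750 to 33781830), a secreted inhibitor of lipoprotein lipase, rose by 4.48 with an implied standard error of 0.94, and Pdk4 (chromosome 6, 5483351 to 5496309), which inhibits pyruvate dehydrogenase, rose by 2.33 with 0.56 in the authors' deposited table. The mitochondrial carrier Ucp3 (chromosome 7, 100472990 to 100486432) rose by 1.82 with 0.33, and Acot1 and Acot2 rose by 1.79 and 1.25 in the authors' deposited table. In G2 against G1, which shares G2, no PPAR target had a positive value. Angptl4, Pdk4 and Ucp3 had -2.96, -1.89 and -1.84 there in the authors' deposited table. Their values for G4 against G2 can therefore not be read as a rise in G4 alone. Of 21 fatty acid oxidation genes all had positive values, the median log2 was 0.39, and 16 were called and 21 adjusted over the list alone (set test adjusted p = 1.02e-70). Decr1 rose by 0.62 and Ech1 by 0.69 in the authors' deposited table.

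Interferon response genes and mitochondrially encoded genes were also higher in G4 than in G2. All 18 interferon genes had positive values with a median log2 of 0.80, and 1 was called, the tetherin gene Bst2 with 1.03 in the authors' deposited table, against 10 adjusted over the list alone (set test adjusted p = 4.18e-14). All 13 mitochondrially encoded genes had positive values with a median of 0.21, with none called over all genes and 7 adjusted over the list alone (adjusted p = 7.67e-09). Endothelial markers had positive values in 17 of 18 members with a median of 0.21, and 1 was called, also adjusted over the list alone, the TGF-beta coreceptor Eng with 0.66 in the authors' deposited table (adjusted p = 6.17e-04, and adjusted p = 0.247 with an assumed correlation of 0.2). Cholesterol synthesis genes had a median of -0.29 with none called, also adjusted over the list alone (adjusted p = 0.00105, and adjusted p = 0.247 with an assumed correlation of 0.2). Adipocyte markers moved with these groups, with a median of 0.35 and calls for Cidea (0.82) and Fabp4 (0.37) in the authors' deposited table, 2 adjusted over the list alone and a set test adjusted p of 0.0201, or adjusted p = 0.314 with an assumed correlation of 0.2.

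For G4 against G2, 200 of the 14539 genes given an adjusted p passed 0.05 in the authors' deposited table, of which 149 rose and 51 fell. The rRNA gene CT010467.1 was among the falls, with -0.59 and an adjusted p of 0.0203 in the authors' deposited table. Further rises under the naming rule were Adnp (2.33), Chrna2 (chromosome 14, 66135039 to 66152948) with 1.66, the gluconeogenic enzyme Fbp2 (1.37), the transcription factor Cebpb (1.33), the peptide transporter Tap1 (1.14), Tiam2 (1.06) and Scand1 (1.05) in the authors' deposited table. The largest falls under the naming rule, which leaves out predicted genes and those under 5 CPM, were Tfcp2l1 (-1.30), Lrrc38 (-1.06), the long noncoding RNA AI480526 (-1.02), Stxbp4 (-1.01), the adenylate cyclase Adcy1 (-0.88) and the histone deacetylase Hdac9 (-0.85) in the authors' deposited table. They were followed by Aldh1l1 (-0.83), B3galt2 (-0.76), Lrrc30 (-0.75), Itm2a (-0.71), the aldehyde oxidase Aox1 (-0.70) and Ctxn3 (-0.70) in the authors' deposited table. Without a filter on low totals the adjusted p was 0.0837 for Adnp, 0.0719 for AI480526 and 0.0600 for Hdac9. After removal of a trend on GC content, transcript length and total it was 0.206 for Scand1, 0.123 for Adcy1 and Hdac9 and 0.0964 for B3galt2.

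**Figure D1:**
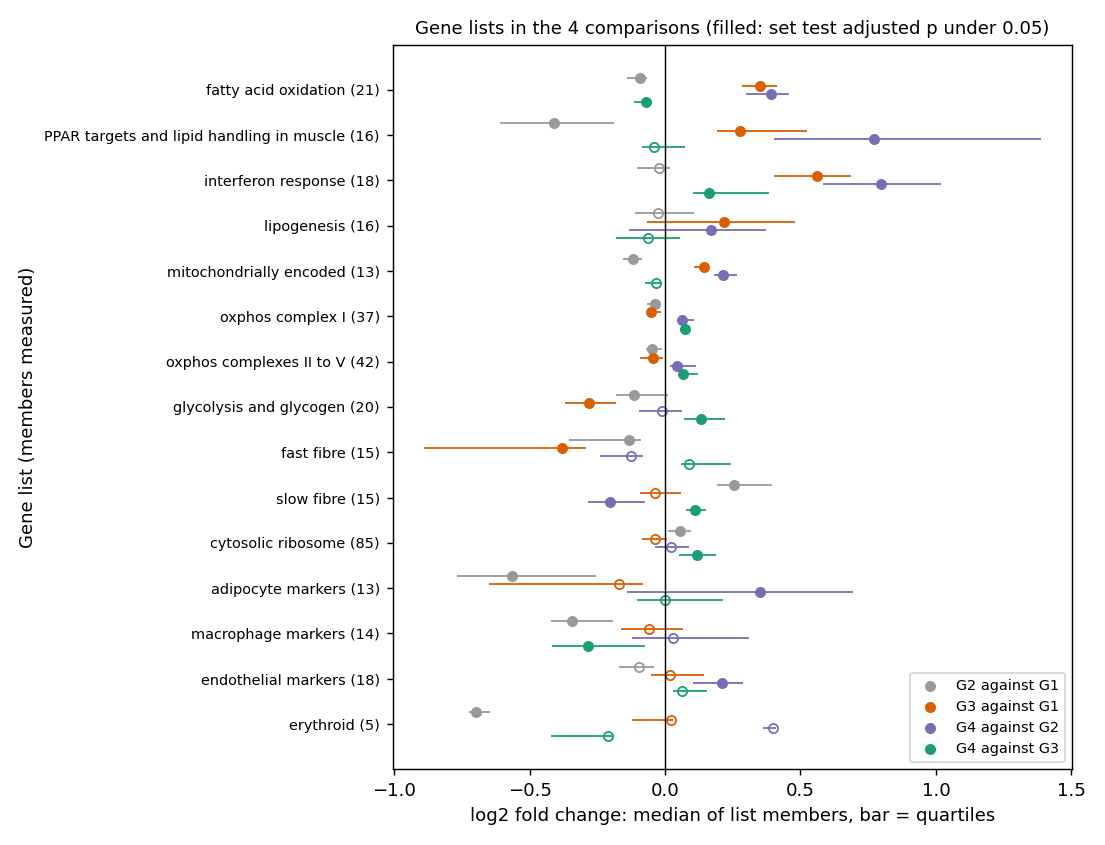
Median log2 fold change (x axis, log2 units) of 15 gene lists (y axis, with the number of measured members) in the 4 comparisons, where bars span the quartiles of the members and filled points mark a set test adjusted p under 0.05. Fatty acid oxidation lay at 0.35 in G3 against G1 and 0.39 in G4 against G2, and PPAR targets at -0.41 in G2 against G1 and 0.77 in G4 against G2.

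The comparisons G3 against G1 and G4 against G2 share no group, and their calls overlapped. Of 49 genes called higher in the authors' deposited table for G3 against G1 and 149 in that for G4 against G2, 41 were shared, where independent lists would share 0.502 (Fisher's exact test, p = 2.81e-76). Of 12 and 51 called lower, 4 were shared against 0.0421 (Fisher's exact test, p = 6.51e-08). Shared genes included Decr1, Ech1, Acot1, Acot2, Chrna2, Abca1 and Srebf1. Across the 9589 genes with a mean of at least 5 CPM, Pearson's r was 0.267 and Spearman's rho 0.206, with a covariance of 0.0106, against a simulated r of 0.00170 for unchanged groups with a range of -0.0924 to 0.0791 over 100 draws. The other pair that shares no group, G2 against G1 and G4 against G3, was related the other way, with a Pearson's r of -0.190, a Spearman's rho of -0.122 and a covariance of -0.00483, against a simulated range of r from -0.0859 to 0.0793. These relations are across genes, which are not independent replicates, and were among 6 computed. The simulated ranges treat genes as independent and are too narrow where genes vary together between mice.

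**Figure D2:**
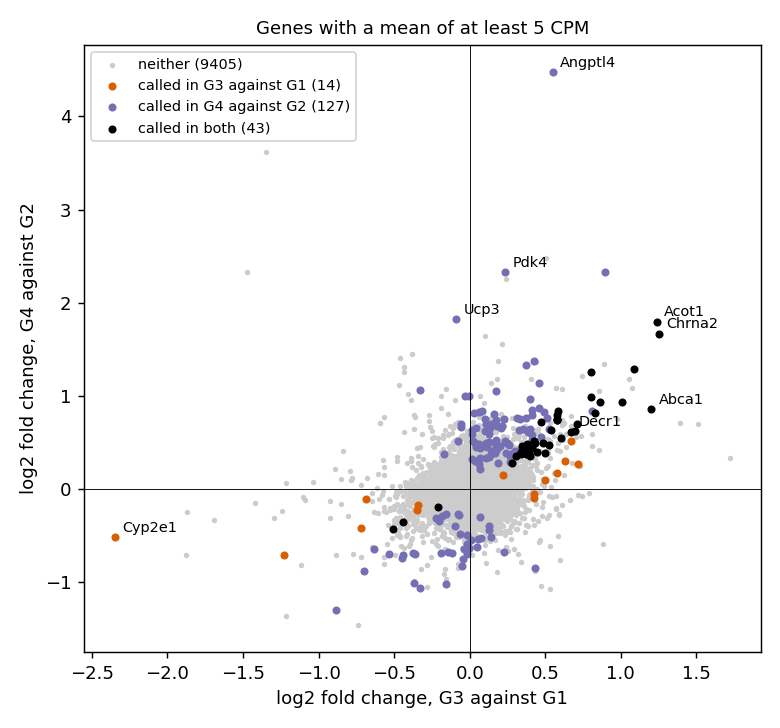
Log2 fold change of G4 against G2 (y axis) against that of G3 against G1 (x axis) for 9589 genes with a mean of at least 5 CPM, with 1 point per gene coloured by which comparison called it. Called in both were 43 genes, among them Acot1, Chrna2, Abca1 and Decr1 in the upper right, while Ucp3, Pdk4 and Angptl4 were called for G4 against G2 and not for G3 against G1, at -0.09, 0.23 and 0.55 on the x axis.

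In G2 against G1, PPAR targets were lower and slow fibre genes higher. Ucp3 was the 1 gene called in the authors' deposited table, with a log2 of -1.84, an implied standard error of 0.33 and an adjusted p of 6.69e-04, a 3.57-fold lower level. None of the 16 PPAR targets had a positive value, the median log2 was -0.41, and 9 were called lower adjusted over the list alone (set test adjusted p = 1.21e-24). The hormone-sensitive lipase Lipe (-0.51), Pdk4 (-1.89) and Angptl4 (-2.96) did not pass over all genes in the authors' deposited table. Slow fibre genes had positive values in 13 of 15 members with a median of 0.26, with none called over all genes and 8 adjusted over the list alone (adjusted p = 4.89e-13). The rebuilt log2 was 0.49 for the slow myosin heavy chain Myh7, with a standard error of 0.14, and 0.42 for the slow troponin Tnni1.

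Fatty acid oxidation genes had a median log2 of -0.09 in G2 against G1 with 0 of 21 positive, and limma's set test called the list as lower (adjusted p = 2.39e-11), with no member called over all genes or adjusted over the list alone. Adipocyte markers moved the same way, with a median of -0.57 and 1 of 13 positive (adjusted p = 1.06e-06), and so did 5 erythroid genes with a median of -0.70 and 3 called adjusted over the list alone (adjusted p = 3.07e-08) and the mitochondrially encoded genes with -0.12 (adjusted p = 1.02e-05). The naming rule also gave haptoglobin Hp (-1.15) and Chrna2 (-0.69) in the authors' deposited table, neither past the threshold. At an unadjusted p under 0.05, 364 genes with a total of at least 100 were counted, 2.35% of them. The table listed only genes with a log2 of 0 or below, so positive values for this comparison were rebuilt from the other 3 tables.

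**Figure D3:**
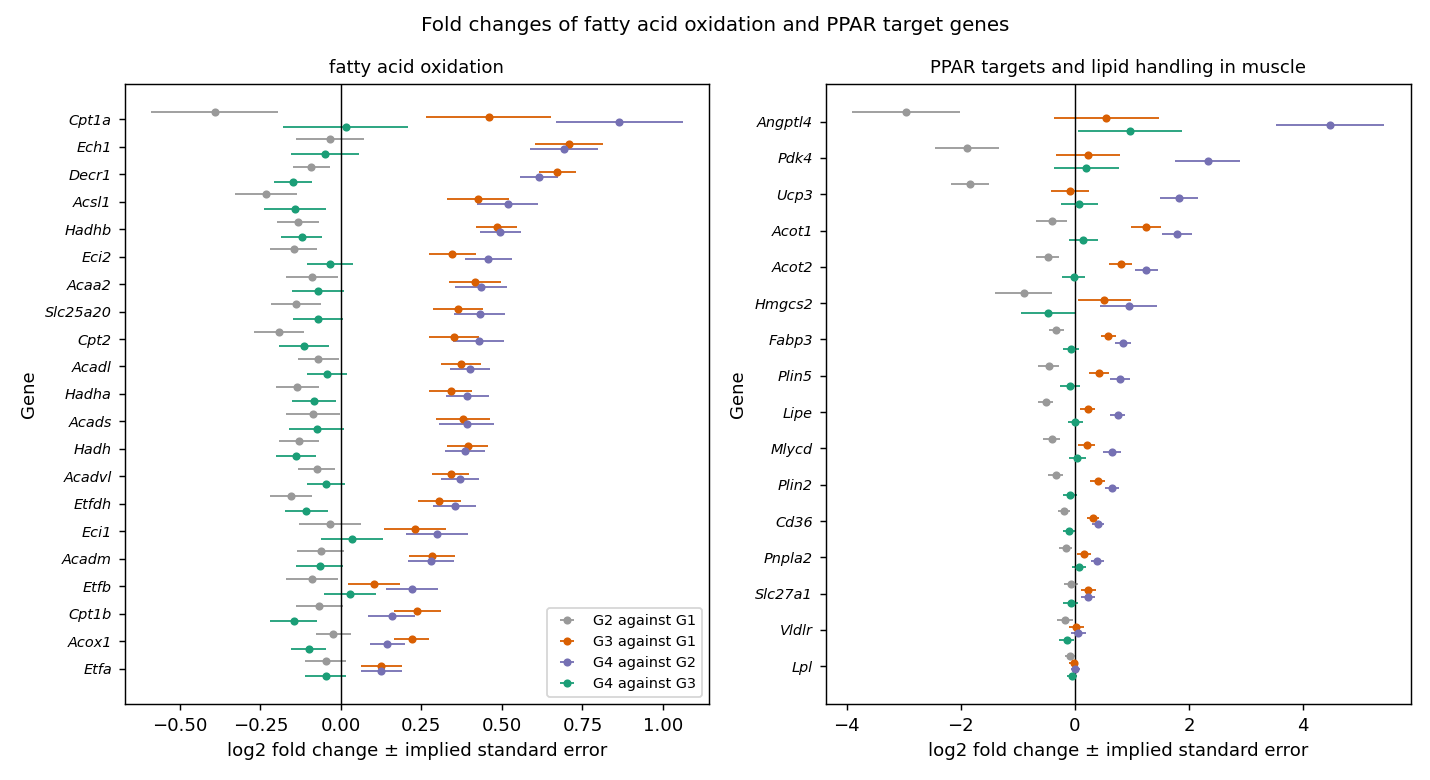
Log2 fold changes (x axis, log2 units) of single genes of the fatty acid oxidation list (left) and the PPAR target list (right) in the 4 comparisons, with points at the deposited or rebuilt value and bars of 1 implied standard error. Decr1 lay at 0.67 for G3 against G1 and 0.62 for G4 against G2, and Ucp3 at -1.84 for G2 against G1 and 1.82 for G4 against G2.

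In G4 against G3, 7 of 17752 genes passed in the authors' deposited table, and all 7 fell. The rRNA gene CT010467.1 (chromosome 17, 39846353 to 39848827), which held 2.89% of all normalised reads, fell by 0.96 with an implied standard error of 0.16, and Mir6236 fell by 0.88 in the authors' deposited table. The mitochondrial leucyl-tRNA synthetase Lars2 (chromosome 9, 123366927 to 123462666) fell by 0.81, and Tbc1d4 (chromosome 14, 101442360 to 101609191), a regulator of insulin-stimulated glucose uptake, fell by 0.43 with 0.10 in the authors' deposited table. Lars2, Mir6236 and the rRNA gene CT010467.1 lay near each other in the other comparisons as well, with log2 values of -0.47, -0.39 and -0.39 in G2 against G1, 0.04, 0.09 and -0.02 in G3 against G1 and -0.29, -0.40 and -0.59 in G4 against G2 in the authors' deposited tables, so the fall of Lars2 is uncertain as a change of that gene alone. The other 3 were Gm20775 (-4.96), Gm32687 (-2.36) and Gm13034 (-1.04) in the authors' deposited table, named after their values were seen. Values that did not pass were -0.35 for Abca8b, -0.37 for Abca2, -0.55 for Slc45a4, 0.81 for Abra and 1.13 for Tiam2 in the authors' deposited table.

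Small shifts of whole lists were called in G4 against G3. Cytosolic ribosome genes had positive values in 78 of 85 with a median log2 of 0.12 (adjusted p = 1.58e-13), respiratory complexes II to V in 40 of 42 with 0.06 (9.39e-07), complex I in 35 of 37 with 0.07 (3.26e-05), and glycolysis and glycogen in 20 of 20 with 0.13 (4.12e-05). None of these members was called over all genes, and 2 ribosome genes were called adjusted over the list alone. The values of this comparison also fell with transcript length (Spearman's rho -0.285 across 15178 genes). After removal of a trend on GC content, length and total, the median was 0.05 for ribosome genes, 0.01 for complexes II to V with an adjusted p of 0.0146, and 0.00 for complex I with an adjusted p of 0.119. With an assumed correlation of 0.2 camera passed none of the 10 lists called in this comparison, with adjusted p = 0.309 for ribosome genes, and 4 lists had an unadjusted p under 0.05.

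The interaction, the difference of G4 against G3 from G2 against G1, which equals that of G4 against G2 from G3 against G1, was rebuilt from the tables and tested in 15494 genes. It called 1 gene, the pseudogene Gm20775, with a rebuilt log2 of -6.73, a standard error of 1.43 and an adjusted p of 0.0357. At an unadjusted p under 0.05, 638 genes were counted, 4.12% of those tested. That share is below the 0.05 that unchanged genes with correct errors would give. Ucp3 had an interaction of 1.91 with a standard error of 0.46 and did not pass (adjusted p = 0.294), and neither did Tecrl (-1.10), Tbc1d4 (-0.53), Hdac9 (-1.28) or Fabp4 (0.54). As a list, PPAR targets had a median interaction of 0.40, positive in 15 of 16 members, with 4 called adjusted over the list alone (set test adjusted p = 2.43e-08). Adipocyte markers moved with them, with a median interaction of 0.54, positive in 11 of 13 members (adjusted p = 0.00131, and adjusted p = 0.252 with an assumed correlation of 0.2). Respiratory complexes II to V were positive in 42 of 42 members with a median of 0.11 (adjusted p = 1.19e-08) and complex I in 37 of 37 with 0.12 (1.35e-06). With the trend on GC content, length and total removed these medians were 0.03 and 0.03, and with an assumed correlation of 0.2 the adjusted p was 0.173 and 0.252. No estimated correlation could be computed for camera without library values, and at an assumed 0.2 the calls that held were 6 of 19 lists in G2 against G1, 6 of 13 in G3 against G1, 4 of 18 in G4 against G2, 0 of 10 in G4 against G3 and 1 of 15 for the interaction, the PPAR targets (adjusted p = 0.0428).

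Whether one comparison countered another was examined for both pairs that share a group with opposite sign. Of the 61 genes called in G3 against G1, 57 had the opposite sign in G4 against G3 (93.4%), and 1 was also called there, Tbc1d4, which rose by 0.43 in the first and fell by 0.43 in the second in the authors' deposited tables. With unchanged groups that share G3, simulation gave 96.8%. In that simulation no gene changed in any group. Of the 61 genes, 59 kept their sign in G4 against G2, which shares no group with G3 against G1. The simulated share is therefore no expectation for genes that changed. The correlation across genes was -0.454 against a simulated -0.500, inside the simulated range of -0.544 to -0.429, and the covariance -0.0136 against -0.0139. Ucp3, called lower in G2 against G1, was called higher in G4 against G2 in the authors' deposited table. For that pair the correlation was -0.608 against a simulated -0.499, outside the simulated range of -0.550 to -0.420, and the covariance -0.0205 against -0.0139. The simulated ranges of both pairs come from errors drawn independently for each gene. They are too narrow where genes vary together between mice. Among the 200 genes called in G4 against G2, 185 had the opposite sign in G2 against G1 (92.5%, simulated 94.4%). The tables hold no library values, so the shared group could not be split and part of either relation may come from it. Neither share lay above its simulated value, and both simulated shares were close to their upper limit. Since the simulation held no changed gene, the shares cannot decide whether one comparison countered the other. The covariance differed from its simulated value by 3.82e-04 for the pair that shares G3 and by -0.00659 for the pair that shares G2.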

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

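The gene lists used in this part were fixed before the data were examined. Their use to weigh explanations, the trend removal and the higher assumed correlation were chosen after the patterns were seen. Only the trend tests of fatty acid oxidation and of PPAR targets in G2 against G1 had an excluding outcome set in advance. That outcome, which would exclude the trend, was set down before the corrected values were seen. Genotype and diet could not be tested as explanations and stay open, because the codes are not tied to the study's groups.

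Fatty acid oxidation genes were higher in G3 than in G1 and in G4 than in G2. More adipocyte RNA in G3 as the whole cause is argued against, since it would raise all abundant adipocyte transcripts, while 11 of 13 markers were negative with a median of -0.17 and an upper quartile of -0.08 where the oxidation genes had a median of 0.35, though Cidea rose there and the marker list itself did not pass its set test (adjusted p = 0.149). In G4 it stays open because the marker median was 0.35 with Fabp4 at a mean of 179 CPM, a gene that muscle capillaries also express. More mitochondria or oxidative fibres in G3 would raise the respiratory genes by about as much, and the median of complexes II to V was -0.043, with an adjusted p of 0.551 at an assumed correlation of 0.2, while the mitochondrially encoded genes had a median of 0.14 with an adjusted p of 0.0563 at that correlation. A trend on GC content, length or expression level as the whole cause is argued against by an adjusted p of 7.73e-65 after its removal, the larger of both comparisons.

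PPAR targets were lower in G2 than in G1. Less adipocyte RNA in G2 may account for part of it and cannot be told apart from a change within muscle fibres, because the adipocyte markers had a median of -0.57. A trend on GC content, length or expression level as the whole cause is argued against by an adjusted p of 1.33e-23 after its removal. The feeding state at dissection could also move Pdk4, Ucp3 and Angptl4, and it stays open because the atrophy and glucocorticoid list gave an adjusted p of 0.262.

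Respiratory chain genes differed between G4 against G3 and G2 against G1 by interaction medians of 0.11 and 0.12. Removal of the trend on GC content, length and expression level left a larger adjusted p of 0.00610 but reduced both medians to 0.03, so most of the size went with the trend and its part cannot be told apart, and the requirement on the medians was added after the corrected values were seen. Members that vary together between mice could produce the calls as well, since the larger adjusted p was 0.252 with an assumed correlation of 0.2.

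The other results whose interaction passed its test are values only. Gm20775 had an interaction log2 of -6.73 at a total of 174 normalised reads. Median interactions were 0.40 for PPAR targets, 0.25 for glycolysis and glycogen, 0.11 for the mitochondrial ribosome, 0.54 for adipocyte markers, 0.25 for fast fibre, 0.45 for atrophy and glucocorticoid response, 0.044 for the cytosolic ribosome and 0.073 for the proteasome. They were 0.095 for antioxidant genes, -0.14 for slow fibre, 0.15 for endothelial markers, 0.085 for the TCA cycle and 0.28 for interferon response. With an assumed correlation of 0.2 the PPAR targets alone among the 15 called lists passed, with an adjusted p of 0.0428.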

How the results depend on the processing

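The filters on total and biotype, the rescaling of z, the trend removal, the assumed correlations and the ranks were alternatives chosen after seeing the data, and the thresholds and the filters by CPM or none before. No direction reversed. With z divided by its robust spread, 6 genes were called in G2 against G1 (1 as deposited) and 15 in G4 against G3 (7), where the spread of z lay under 1. Under this rescaling 8 results for named genes passed newly and 3 no longer passed. The spread lay above 1 in G4 against G2 (1.07), where rescaling can only remove calls. A minimum fold of 1.5 gave 25 genes in G3 against G1 (61) and 118 in G4 against G2 (200), by its own construction. In G4 against G3 an adjusted p under 0.1 gave 15 genes, a mean of at least 5 CPM gave 4, and protein-coding genes alone gave 2. Both filters themselves remove called genes. Of the 7 called genes 3 are protein-coding, so the changed adjustment also removed a call there. The interaction gave 0 genes with no filter, at a mean of at least 5 CPM and among protein-coding genes (1, Gm20775, as rebuilt). At an unadjusted p under 0.05 it had 638 genes, 4.12% of those tested. The setting with no filter adds genes to the adjustment, and the others leave Gm20775 out. Called lists with an assumed correlation of 0.2 numbered 6 in G2 against G1 (19), 6 in G3 against G1 (13), 4 in G4 against G2 (18), 0 in G4 against G3 (10) and 1 for the interaction (15), and with 0.05 they numbered 6 in G4 against G3 and 8 for the interaction. Trend removal left 9 lists for the interaction, and the cause was not tested. Of results for named genes 392 kept their side of the threshold, 9 passed it newly and 10 no longer passed, and of list results 198 kept it and 102 no longer passed. No paired analysis was possible because the tables hold no library values. For the same reason the fit of only the compared libraries, other size factors, other count tests, a limma refit, leaving out each replicate, the block of animal numbers, other pseudocounts, camera with an estimated correlation, fry and other splits of the samples were not run. Depth limits Nox1, with 26 reads in all.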

Other observations

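The gene lists in this part were fixed before the data were examined, and the call of CT010467.1 in G4 against G2 is the authors' own. The other choices in this part were made after the results were seen, among them the averages, the higher assumed correlation and which results to report. Averaged over G2 against G1 and G4 against G3, 7 genes were called in the rebuilt values, 1 higher and 6 lower, against 255 genes, 187 higher and 68 lower, for the average of G3 against G1 and G4 against G2. The values of the first pair were related negatively across genes (r of -0.190) and those of the second positively (0.267), so the first average partly cancels opposite values and its count is no measure of how much changed in either comparison. In the first average CT010467.1 fell by 0.67, Lars2 by 0.64, Mir6236 by 0.63 and the transporter Mfsd4a by 0.61, with implied standard errors of 0.11 to 0.14. In the second average the MHC class I gene H2-Q7 rose by 1.11, and the AMP-activated kinase subunit Prkag3 fell by 0.97 and Mpp3 by 0.73, all rebuilt.

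In G4 against G3 the list of atrophy and glucocorticoid response had a median log2 of 0.32, with positive values in 14 of 17 members (adjusted p = 0.00447, and adjusted p = 0.465 with an assumed correlation of 0.2). Macrophage markers had a median of -0.28 (adjusted p = 0.0103, and adjusted p = 0.465 with that correlation). In G3 against G1 all 14 immediate early genes had positive values with a median of 0.34 (adjusted p = 3.45e-04, and adjusted p = 0.124 with that correlation). Schwann cell and nerve genes had a median of -0.25 in G2 against G1 and -0.28 in G3 against G1, with adjusted p of 0.00230 and 0.0389, and with that correlation of 0.154 and 0.516.

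The rRNA gene CT010467.1, the antisense gene Gm15564, Mir6236 and Lars2 had log2 values of -0.96, -1.02, -0.88 and -0.81 in G4 against G3 and of -0.39, -0.46, -0.39 and -0.47 in G2 against G1 in the authors' deposited tables. In G4 against G2 they had -0.59, -0.64, -0.40 and -0.29 in the authors' deposited table, where CT010467.1 was called, and in G3 against G1 -0.02, -0.08, 0.09 and 0.04 with none called. Mitochondrially encoded genes held 20.1% of all normalised reads and the 10 most abundant genes 24.3%. The robust spread of z was 0.80 in G2 against G1 and 1.07 in G4 against G2, where 1 is the value for unchanged genes with correct errors. Spearman's rho of the change with transcript length across 15178 genes was 0.173 in G3 against G1, -0.161 in G4 against G2 and -0.285 in G4 against G3.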
